A study of Mus musculus with 2 samples.

How the data were processed

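Total RNA sequencing was done on 2 pools of E16.5 mouse forebrain, and each pool has 1 gene table and 1 transcript table. Per the labels, RNA was extracted with a mirVana kit, and a manual for a SMARTer Ultra Low RNA kit is among the listed protocols. Per the notes deposited with each sample, reads were aligned to mm10 and quantified on transcripts of GENCODE M4, with 1 table per library and no pooling of replicates. The aligner, the quantification program and their versions are not given in the sources used here; the column names are those that RSEM writes. The authors deposited estimated counts (expected counts) per gene and per transcript, as maximum likelihood values and as posterior means, without normalization, per the file headers. The authors deposited TPM values scaled to the same fixed sum over all listed features of each library, spike-ins included, per the file headers and the column sums. The deposited FPKM values are per kilobase of effective length and scaled to the reads of the library, per the file headers. Each transcript's percent of its gene was deposited by the authors as well, per the file headers. Because TPM was scaled with spike-ins inside, the spike-in share lowers the TPM of all other genes, by more in replicate 1 (5.93% of TPM) than in replicate 2 (4.10%).

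The tables list 43346 genes with Ensembl identifiers, 97 spike-in sequences (96 of them ERCC) and 26248 tRNA-like features. Gene symbols, types and coordinates came from GENCODE M21, which uses GRCm38, the same assembly as mm10, through the identifier without its version. Of the genes, 42462 matched. A symbol with several identifiers, of which there were 40, was not used. The authors' library totals on genes, 31211128 and 26957198 expected counts, set the depth. A count of 0 allows up to 3 counts, which for an effective length of 2 kb equals 0.0799 TPM in replicate 1 and 0.0952 TPM in replicate 2.

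The 2 libraries are biological replicates of 1 group, so no groups were compared and no p-value was computed. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, which gave trimmed mean (TMM) scaling factors and the common biological coefficient of variation. Log2 ratios are replicate 2 minus replicate 1, of scaled counts with a prior count of 0.5. A gene was counted as differing when its mean count was at least 50, its ratio at least 2-fold and its 95% exact Clopper-Pearson counting interval excluded equality. Such intervals cover counting error only, since reads amplified by PCR are not independent molecules. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

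Before the data were examined, 38 gene lists, 20 gene pairs and 20 genes for transcript usage were fixed, together with the rule for naming genes. The rule takes the 20 protein-coding nuclear genes of highest TPM, the 3 highest members and the lowest member of each list, the 10 largest differences in each direction, all pairs and transcript genes, and members of lists that stand apart. Hoxa2, Hoxb4 and Miat, and the named members of the lists written later, fall outside this rule and were chosen after their values were seen. Some genes and pairs that the rule takes are not reported here. The level of a list was its median TPM, placed among 10000 random lists of protein-coding genes. The difference of a list between libraries was the median log2 ratio of members with a mean of at least 50 counts, placed among 10000 random lists matched on mean expression in 20 bins. At least 4 such members were required, which left 36 lists. A pair was called different from equality when both libraries had the same sign and the mean exceeded 3 SD. Transcript usage covered genes at 10 TPM or more in both libraries with at least 2 listed transcripts.

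The procedures were tested on simulated data with the real means and library sizes. With no gene changed, counting noise gave 1 call, and counting noise with the measured coefficient of variation gave 11 calls among 13909 genes. That coefficient was common to all genes and came from these same libraries, so the 11 calls are not a rate of false calls for the real data. Of 200 genes changed 2-fold, 3-fold or 4-fold, 53.5%, 95.0% and 96.0% were called. Of 100 simulated lists of 8 genes, 7 stood apart with no shift and 100 with a log2 shift of 0.5. These lists were random genes with independent noise, and smaller shifts were not simulated. Alternatives covered the TPM minimum, the pseudocount, FPKM, posterior means, 2 other scalings, the count minimum, the matching of random lists and each replicate left out. Spike-in scaling and a restriction to protein-coding genes were chosen after seeing the data.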

Results

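Forebrain RNA was measured in mouse embryos of the B6NCrl strain at 16.5 days of gestation, an age at which cortical neurons are still being born. Tissue from male and female embryos was pooled, and total RNA longer than 200 nt was sequenced from 10 ng of starting material with added ERCC spike-in RNAs. The series holds 1 group with 2 biological replicates, each a separate pool. The second pool came from 41 embryos. The gene tables summed to 31211128 expected counts on genes in replicate 1 and 26957198 in replicate 2. With no second tissue or age, the design allows a description of the forebrain transcriptome and a comparison of its 2 pools. Levels are given as mean ± SD (n = 2), and no test between conditions was possible.

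The forebrain libraries were led by cytoskeletal genes of growing neurons. Tuba1a, an alpha-tubulin of migrating and axon-forming neurons (chromosome 15, 98949837 to 98953703), had the highest level of the protein-coding nuclear genes at 15419 ± 89.8 TPM. Stmn1, a regulator of microtubule assembly, followed at 6786 ± 293 TPM, then Actb at 6033 ± 117 TPM and Tmsb4x, an actin-binding peptide, at 5820 ± 715 TPM. Globin messages of circulating red blood cells also ranked among the 20 highest, with Hba-a2 at 5249 ± 902 TPM and Hbb-bs at 3056 ± 514 TPM. The imprinted gene Nnat reached 5213 ± 1074 TPM. Tubulin genes and the pair Hba-a1 and Hba-a2 have near-identical copies, so the division of reads within these families is uncertain. At 1 TPM or more in both libraries, 14802 of 43346 listed genes were detected. These held 13038 of 21474 protein-coding genes, 961 of 6853 long noncoding genes and 559 of 7906 pseudogenes.

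Markers of young neurons and of dividing progenitors were both abundant. All 12 pan-neuronal genes exceeded 10 TPM in both libraries, with a median of 325 TPM, and were led by Tubb3 at 1609 ± 83.7 TPM, Stmn2 at 729 ± 43.6 TPM and Gap43 at 707 ± 138 TPM. The 12 cell cycle genes had a median of 68.2 TPM, from Mki67 at 14.3 ± 2.81 TPM to Pcna, the DNA polymerase clamp, at 150 ± 18.3 TPM. Of the 13 radial glia genes, which mark the neural stem cells of the ventricular zone, 11 exceeded 10 TPM in both libraries. Fabp7, a fatty acid binding protein of these cells, reached 1314 ± 201 TPM, Vim 406 ± 87.3 TPM and Slc1a3 112 ± 14.9 TPM. Intermediate progenitors of the cortex were represented by Gadd45g at 101 ± 0.177 TPM and Neurog2 at 52.4 ± 11.3 TPM. The medians of these lists lay at the 100, 99.94, 99.65 and 96.98 percentiles of random lists of protein-coding genes.

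Both excitatory and inhibitory neuron lineages were present. The glutamatergic list had a median of 42.0 TPM and was led by Neurod6 at 439 ± 70.5 TPM and Neurod2 at 102 ± 14.7 TPM, transcription factors of differentiating cortical neurons. Deep layer genes had a median of 41.5 TPM, with Sox5 at 185 ± 8.15 TPM and Bcl11b at 70.5 ± 4.62 TPM. Upper layer genes had a median of 23.1 TPM, with Cux1 at 116 ± 3.32 TPM and Pou3f2 at 44.7 ± 6.68 TPM. All 14 members of the GABAergic and ganglionic eminence list were detected, led by the peptide gene Sst at 231 ± 22.7 TPM, Dlx1 at 197 ± 6.22 TPM and the peptide gene Npy at 139 ± 2.01 TPM. Striatal projection neuron genes had a median of 30.1 TPM, with Meis2 at 125 ± 5.26 TPM, Foxp1 at 99.8 ± 3.74 TPM and the peptide gene Tac1 at 66.7 ± 9.86 TPM. Cajal-Retzius genes were lower, with a median of 4.68 TPM, although Calb2 and Reln reached 63.2 ± 19.7 TPM and 49.2 ± 0.255 TPM. The synaptic machinery was already transcribed, with Gria2 at 225 ± 4.41 TPM, Vamp2 at 200 ± 22.9 TPM and Snap25 at 127 ± 19.2 TPM.

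Glial and vascular genes were present at lower levels. Of the 8 myelin genes, 5 were at 1 TPM or more in both libraries and 2 at 10 TPM or more. Their median was 6.52 TPM, with Cnp at 22.1 ± 3.88 TPM and Mobp at 0.045 ± 0.021 TPM. Cldn11 reached 45.5 ± 13.1 TPM, but its log2 ratio between the libraries, 0.57, was opposite in sign to the list's median of -0.38. Its level may therefore not stand for the other myelin genes. Gfap, an intermediate filament of mature astrocytes, was at 1.51 ± 0.650 TPM and Aqp4 at 1.15 ± 0.403 TPM, whereas Aldoc reached 143 ± 22.2 TPM. All 9 microglia genes and all 9 endothelial genes were detected, with medians of 11.8 and 11.2 TPM. Among them were C1qb at 23.6 ± 4.98 TPM and Cldn5 at 82.6 ± 9.87 TPM. Oligodendrocyte precursor genes had a median of 4.35 TPM and were led by Olig1 at 30.2 ± 4.00 TPM. Ttr, the transport protein secreted by the choroid plexus, reached 396 ± 36.0 TPM.

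Regional markers were mainly those of the telencephalon, with lower levels of diencephalic ones. All 12 telencephalon patterning genes were detected, with a median of 56.5 TPM, among them Lmo3 at 174 ± 7.67 TPM and Lmo4 at 154 ± 12.2 TPM. None of the 14 midbrain and hindbrain genes reached 1 TPM in both libraries, and 7 of them, among them Hoxa2 and Hoxb4, had 0 counts in both. Their median lay at the 0.32 percentile of random lists. Thalamic genes had a median of 7.22 TPM, led by Tcf7l2 at 35.6 ± 18.6 TPM. Of 12 genes of eye, nose, pituitary, skin and muscle, only Acta1 reached 1 TPM in both libraries, at 5.44 ± 0.184 TPM.

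**Figure D1:**
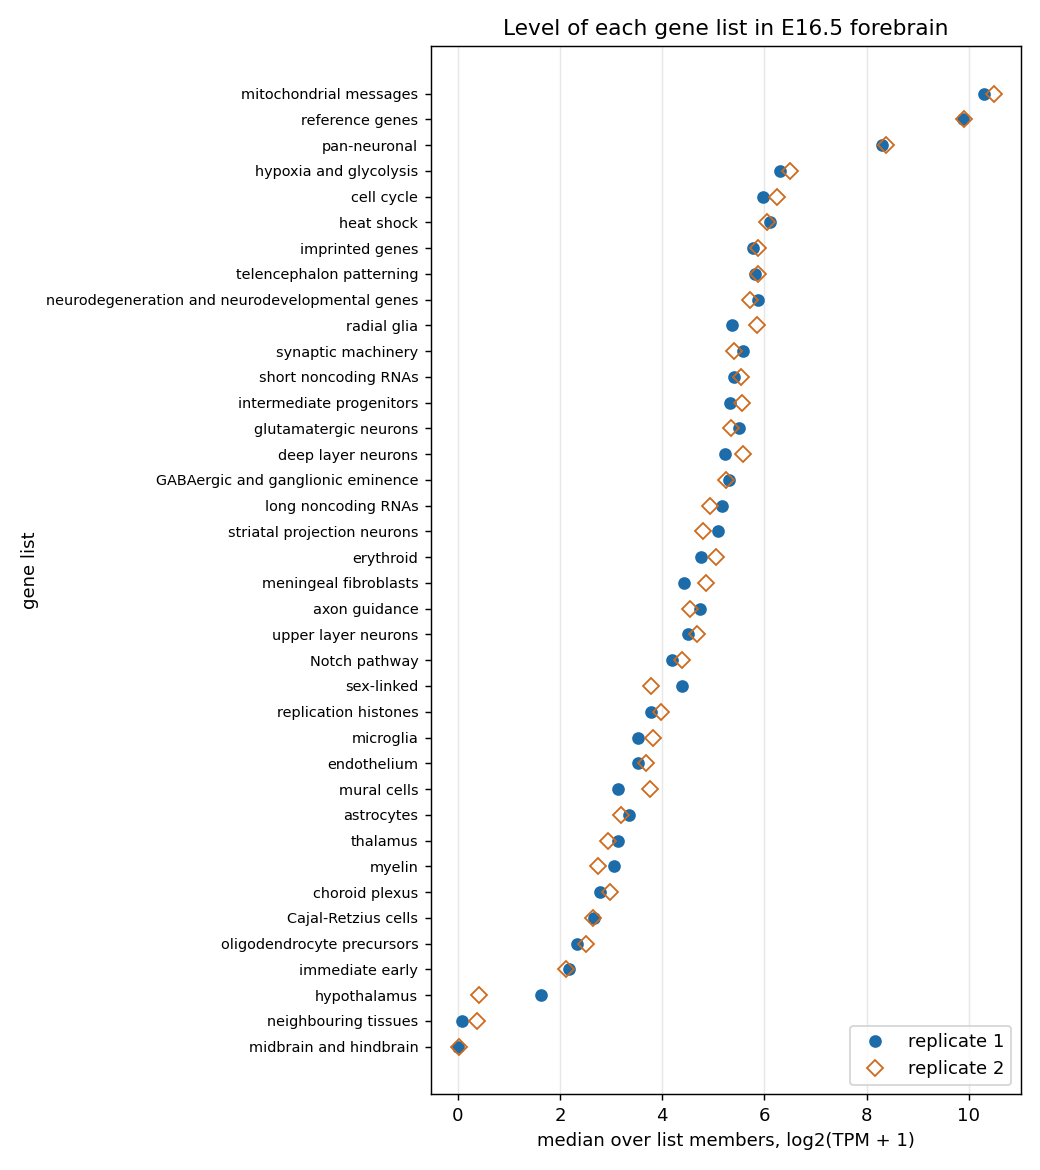
Median level of each of the 38 gene lists, as log2(TPM + 1) on the horizontal axis, with circles for replicate 1 and open diamonds for replicate 2. Pan-neuronal genes, at a median of 325 TPM, lie near the top, and midbrain and hindbrain genes, at 0.0075 TPM, lie at the bottom.

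Protein-coding genes held 93.0 ± 0.582% of expected counts, long noncoding genes 1.81 ± 0.136% and the mitochondrial genome 1.46 ± 0.116%. By TPM, which corrects for length, the protein-coding share was 81.8%. The nuclear long noncoding RNA Malat1 was at 4656 ± 1676 TPM, and Pantr1, which neighbours Pou3f3, at 404 ± 44.4 TPM. The 7SL RNA copies Rn7s1 and Rn7s2 were listed at 12049 ± 207 and 12049 ± 206 TPM, but share nearly all of their reads, so their separate values are uncertain. All 20 imprinted genes were detected, led by Nnat, Meg3 at 970 ± 400 TPM and Ndn at 852 ± 236 TPM. Replication histones, whose messages lack poly(A) tails, were led by Hist1h4d at 161 ± 19.4 TPM. The 353 listed genes typed as nuclear rRNA held 0.0001% of expected counts. That share covers annotated genes only and does not measure the rRNA content of the libraries. How completely the libraries captured RNA without poly(A) tails was not tested.

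Ratios of paired genes within a library compared early with mature forms and 1 lineage with another. Grin2b, the fetal subunit of the NMDA receptor, exceeded Grin2a by a log2 ratio of 4.68 ± 0.69. Camk2b exceeded Camk2a by 3.25 ± 0.54, and Vim exceeded the mature glial filament Gfap by 8.12 ± 0.33. Definitive globins were far above their embryonic counterparts, with log2 ratios of 7.84 ± 0.38 for Hba-a1 over Hba-x and 7.25 ± 0.18 for Hbb-bs over Hbb-y. Ptbp2, the neuronal splicing regulator, exceeded Ptbp1 by 1.26 ± 0.06. Dcx exceeded the later neuronal marker Rbfox3 by 3.02 ± 0.33, and Dlx2 exceeded Eomes by 1.18 ± 0.21. In contrast, Olig2, of the oligodendrocyte precursor list, was below the myelin gene Mbp, at -1.29 ± 0.43. The transcripts of Mbp were not examined, and only 5 of the 8 myelin genes reached 1 TPM in both libraries. This pair alone therefore does not show mature oligodendrocytes. Of the 20 pairs, 16 had the same sign in both libraries and a mean above 3 SD. The exceptions included Slc12a2 over Slc12a5 at -1.0 ± 0.69, Slc17a6 over Slc17a7 at 1.13 ± 0.40 and Xist over Ddx3y at 0.82 ± 0.80. An exact sign test over 2 libraries cannot give a p below 0.5, so none was run.

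**Figure D2:**
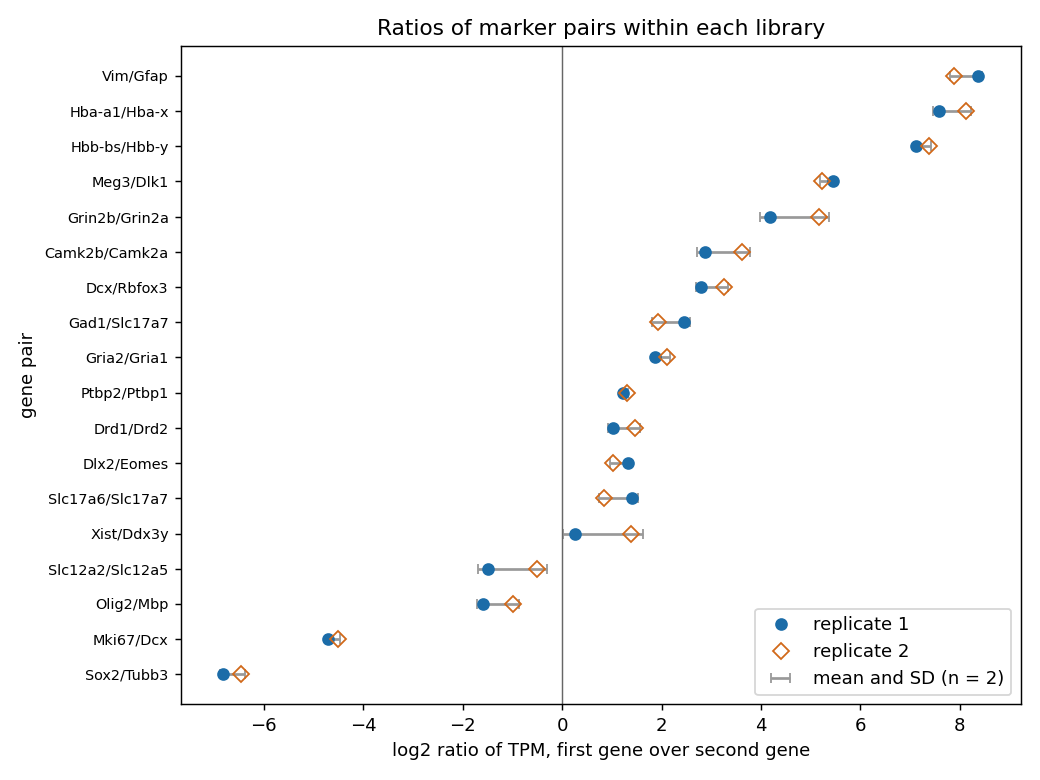
Log2 ratio of TPM of the first gene over the second for the pairs reported, with circles for replicate 1, open diamonds for replicate 2 and bars for mean and SD (n = 2). Grin2b over Grin2a lies at 4.68 and Sox2 over Tubb3 at -6.63.

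The leading transcript of a gene was mostly the same in both pools. Among 6833 genes at 10 TPM or more with at least 2 listed transcripts, the most abundant transcript was the same in 92.8%, and in 32.9% it held at least 80% of the gene's TPM in both libraries. Pkm, which encodes pyruvate kinase and carries a pair of mutually exclusive exons, was split evenly. Transcript ENSMUST00000163694, which holds the upstream alternative exon (chromosome 9, 59675029 to 59675195), made up 52.8% of Pkm in replicate 1 and 48.7% in replicate 2. Transcript ENSMUST00000034834, with the downstream exon (59675568 to 59675734), made up 47.2% and 51.3%. Ncam1 was dominated by an 18-exon transcript, Ncam1-204, at 84.6 ± 1.75%, and Rbfox1 by Rbfox1-202 at 87.4 ± 0.693%. Cdc42 divided between Cdc42-202 at 52.8 ± 4.00% and Cdc42-201 at 47.2 ± 4.00%. In Mapt, which encodes the microtubule protein tau, Mapt-205 held 47.5 ± 4.07% and Mapt-204 38.0 ± 0.332%. Other shares differed more between the pools, with the Clasp2 transcript ENSMUST00000166734 at 17.0% in replicate 1 and 30.1% in replicate 2 and Tpm1-211 at 11.8% and 23.1%. Of Agrn, 50.3 ± 0.0778% was assigned to Agrn-205, a transcript annotated as a retained intron. Such shares come from the authors' model-based division of reads and are least certain for transcripts that differ by little sequence.

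The pools resembled each other closely for most genes and differed in a limited set. Across 43346 genes, Pearson's r of log2(TPM + 1) was 0.993 and Spearman's rho 0.948; genes are not independent replicates, so no p is given. The biological coefficient of variation was 12.3%, and 98.6% of 13927 genes with a mean of at least 50 counts lay within 2-fold of each other. Their counts did not agree within sampling noise, with a chi-square of 18.5 per degree of freedom, a measure that does not separate pool, preparation and amplification. All differences below are between these libraries, with no replicate check, and are relative to the trimmed mean scaling. Scaling by spike-ins would move every gene by 0.56 on the log2 scale towards replicate 2.

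Genes of the hypothalamus and several of the thalamus were lower in replicate 2. The 5 hypothalamic genes with enough counts had a median log2 ratio of -2.06, where the central 95% of random lists matched on expression ran from -0.60 to 0.36. Sim1, a transcription factor of the paraventricular nucleus, was at 1.14 TPM in replicate 1 and 0.16 TPM in replicate 2, with a log2 ratio of -2.85 (95% counting interval -3.67 to -2.17). The vasopressin gene Avp was at 19.6 and 3.98 TPM, Otp at 2.17 and 0.52 TPM and Trh at 7.59 and 3.21 TPM. All 6 thalamic genes compared had ratios below 0, with a median of -0.53 and Tcf7l2 at 48.8 and 22.5 TPM. Under spike-in scaling the thalamic median was 0.030. It was -0.88 at a minimum of 20 counts and -0.18, within its random range, at 200, where too few hypothalamic genes remained for a value. Of the 6 thalamic genes, Tcf7l2, Gbx2 and Lhx9 had log2 ratios of -1.05, -0.98 and -0.88, whereas Prox1, Rora and Lef1 were nearer 0 at -0.18, -0.12 (-0.35 to 0.11) and -0.07 (-0.24 to 0.10). Sox14, with too few counts to be among the 6, had -0.92. The midbrain and hindbrain list, too low for the comparison of lists, went the other way, with 22 summed counts in replicate 1 and 131 in replicate 2, a log2 ratio of 2.80 (2.14 to 3.52). Gata3 held most of them, with 16 and 93 counts, and Pax5 had 3 and 13 and En1 1 and 13.

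Connective tissue, blood and progenitor genes were higher in replicate 2. All 9 meningeal fibroblast genes were higher there, with a median log2 ratio of 0.79. Col1a1 was at 37.5 TPM in replicate 1 and 141 TPM in replicate 2, and Col1a2 at 35.8 and 101 TPM. Erythroid genes had a median of 0.32, microglia genes 0.34 and endothelial genes 0.23. All 12 cell cycle genes were higher in replicate 2, with a median of 0.28, as were 11 of 12 radial glia genes, with a median of 0.26, and 6 of 7 intermediate progenitor genes, with 0.24. Glutamatergic genes had a median of 0.23 and Notch pathway genes 0.17. Astrocyte genes had a median of 0.46, and of 0.30 and 0.26 at minimums of 20 and 200 counts.

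Synaptic, pan-neuronal and imprinted genes were lower in replicate 2 relative to other genes. Of 14 synaptic genes 13 were lower, with a median of -0.30 and with Syp at 134 TPM in replicate 1 and 102 TPM in replicate 2. Pan-neuronal genes had a median of -0.17, myelin genes -0.38 and genes of brain disorders -0.14. The summed counts of the myelin list had a log2 ratio of -0.016 (-0.083 to 0.051), with Cldn11, its most abundant member, at 0.57. Of 19 imprinted genes 13 were lower, with a median of -0.32. Magel2 had a log2 ratio of -1.47 and Meg3 -1.11, whereas Igf2 and H19 had 0.57 and 0.60. These 5 medians were above 0 under spike-in scaling, which keeps their order. Y-linked genes were lower in replicate 2, with Ddx3y at 20.0 and 12.7 TPM, Eif2s3y at 45.9 and 27.0 TPM and Kdm5d at 10.2 and 6.22 TPM. Xist, transcribed from the inactive X of female cells, was at 23.8 and 33.2 TPM. The median of the sex-linked list was -0.63, while its summed counts had a log2 ratio of 0.15 because Xist holds most of them. Of 36 lists compared, 18 lay outside the central 95% of their random lists. By chance 1.80 would if list members varied independently, and 7 of 100 simulated lists with no shift did, also under independent noise. Genes of a real list can vary together, so neither figure is a chance rate for these lists.

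**Figure D3:**
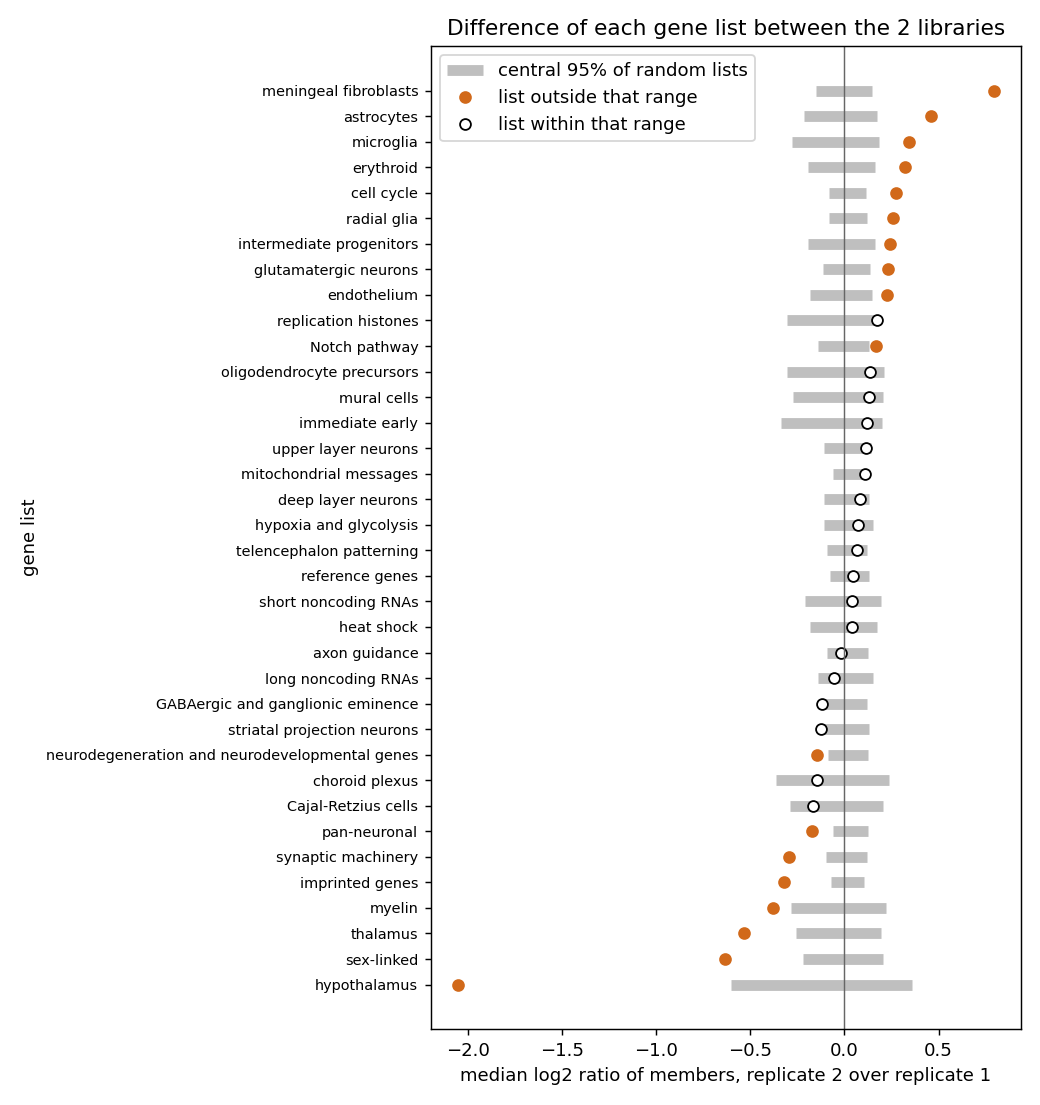
Median log2 ratio of replicate 2 over replicate 1 for the members of each of 36 gene lists (points), with grey bars for the central 95% of 10000 random lists matched on expression. Meningeal fibroblast genes lie at 0.79 and hypothalamic genes at -2.06, and on spike-in scaling every point and every grey bar would shift by 0.56 to the right.

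Single genes differed by at least 2-fold in 195 of 13927 cases, with 51 higher in replicate 2 and 144 higher in replicate 1. The largest difference towards replicate 2 was Bpifa1, a secreted protein of the airway epithelium (chromosome 2, 154142880 to 154149219), with 2 and 267 counts and a log2 ratio of 6.97 (5.42 to 10.34). Ibsp, a bone matrix protein, followed at 4.13 (3.56 to 4.82), and Cnmd, a protein of cartilage, at 3.59 (2.82 to 4.59). Hapln1 and Col9a1, which encode cartilage matrix proteins, had 3.01 and 2.08, Aldh1a1 3.47, Gata3, of the midbrain and hindbrain list, 2.73 and Aspn 2.45. Towards replicate 1, the 10 largest differences included Sim1 and the neuropeptide genes Crh at -2.49, Avp at -2.30 and Gal at -2.11. The processed pseudogene Gm10233 had 313 counts in replicate 1 and 0 in replicate 2, and pseudogene values are uncertain because of reads shared with parent genes. With spike-in scaling 535 genes passed, 514 of them higher in replicate 2, and with a minimum of 20, 200 or no counts the number was 474, 40 or 1099.

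**Figure D4:**
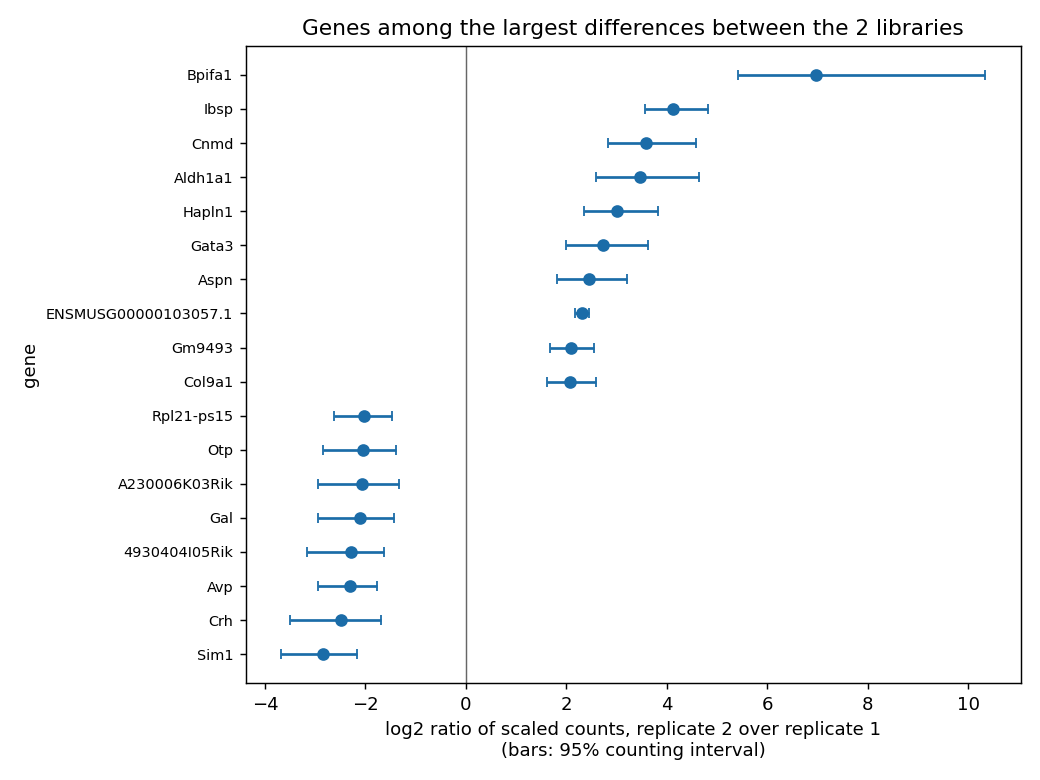
Log2 ratio of scaled counts, replicate 2 over replicate 1, for the reported genes among the 10 largest differences in each direction, with 95% counting intervals as bars. Bpifa1 lies at 6.97 and Sim1 at -2.85, and Gm10233, with 0 counts in replicate 2, has no finite interval and is not drawn.

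Most classes of long noncoding genes were lower in replicate 2, while processed pseudogenes were more often higher. Unprocessed pseudogenes were not, with medians of -0.06 over 15 transcribed ones and -0.008 over 15 others. Among the genes at least 2-fold apart, 53 long noncoding genes were higher in replicate 1 and 0 in replicate 2, against 83 and 36 protein-coding genes and 5 and 12 pseudogenes. The median log2 ratio was -0.26 over 202 lincRNA genes and -0.56 over 132 TEC genes, a class of unverified transcripts, against 0.01 over 12881 protein-coding genes and 0.15 over 193 processed pseudogenes. The long noncoding genes counted here include both classes. They also include 165 antisense, 135 processed transcript, 25 bidirectional promoter and 18 sense-intronic genes with enough counts, so the class is mixed. The fixed list of named long noncoding RNAs did not stand apart, with a median of -0.05 and 4 of 8 members higher in replicate 2. Malat1 was at 5841 TPM in replicate 1 and 3470 TPM in replicate 2, and Miat at 46.0 and 26.0 TPM. Snhg11 (chromosome 2, 158375638 to 158386145), a small RNA host gene that the annotation used here types as protein-coding, was at 177 and 41.1 TPM, a log2 ratio of -2.0 (-2.06 to -1.94). Pantr1 and Xist, in contrast, had log2 ratios of 0.22 and 0.43. Antisense genes are uncertain, since the strand setting of the authors' counting is not given in the sources used here.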

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

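Among the tests in this part, the comparison with lists matched on length, planned as an alternative, was taken as a test of the hypothalamic result only after that result was seen, and the transcript test on nonsense-mediated decay was added once the retained-intron result was known. Signal in features outside the comparisons came from the spike-ins, which held 2.40% of counts in replicate 1 and 1.62% in replicate 2, and from tRNA features, with 11.7 and 8.0 expected counts. Across 46 spike-ins compared, all 46 were lower in replicate 2, with a median log2 ratio of -0.58 and an SD of 0.17.

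Hypothalamic genes were higher in replicate 1. The tables argue against a trend with expression or gene length, since the list lay at the 0.00 percentile of random lists matched on both, whose central 95% ran from -0.61 to 0.36. The list was singled out at that percentile of lists matched on expression alone. Only the length part is therefore new, and it rests on the same 5 genes. A candidate explanation is more diencephalic tissue in that pool. A second list of hypothalamic genes, whose ratios had not been examined, had a median of -0.72, against a random range of -0.56 to 0.22, with 13 of 15 members lower in replicate 2. For this list the minimum mean count was set to 5 after too few members reached 50, before its ratios were seen, and its summed counts had a log2 ratio of -0.14. Arnt2, at -0.10, holds most of that sum, with 6218 of 6804 counts in replicate 1 and 4964 of 5271 in replicate 2. The design names no biological difference between the pools, so no biological explanation was tested.

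Bone and cartilage genes such as Ibsp and Cnmd were higher in replicate 2. Skull or nasal tissue in that pool could account for this, and 16 of 17 members of a second bone and cartilage list were higher there, with a median of 1.38 at a minimum count of 5 and 0.46 over 5 members at 50. The summed counts, the measure chosen beforehand, had a log2 ratio of 0.35 (0.29 to 0.42), short of the size set for them, and Col9a3, with 1810 of 3332 counts in replicate 1, was near 0 at 0.03. More meninges alone stays open as well, because the list's median exceeded that of the meningeal list by 0.59 with a bootstrap interval of -0.21 to 1.97 over members that differ widely. Against it go Matn1, with 1 and 85 counts and a log2 ratio of 6.06 (4.12 to 11.95), and Acan, with 11 and 81 counts and 3.05 (2.19 to 4.16). Both lay above Col1a1, the highest gene of the meningeal list, at 1.88 (1.82 to 1.93). Bglap2 had 0 and 11.0 counts and a ratio of 4.75 (from 1.55). These are among the highest members of the list and had few counts in replicate 1, and the more abundant Alpl and Col11a1, at 0.46 and 0.47, lay below the meningeal median of 0.79. In the list of eye, nose, pituitary, skin and muscle genes, all 6 members with at least 10 counts in total were higher in replicate 2, with a median of 2.16 and a summed-count ratio of 0.67 (0.39 to 0.96). Neither explanation was settled by the measure set for it, and no biological explanation was tested.

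As annotated classes, lincRNA, TEC and sense-intronic genes were mostly lower in replicate 2, although the fixed list of 8 named long noncoding RNAs, at a median of -0.05, lay within its random range. The tables argue against a change of the protein-coding genes they overlap, since 108 TEC and sense-intronic genes with 1 such gene differed from it by a median of -0.66 (-0.73 to -0.59), 101 of them downwards. They also argue against a general loss of short or incomplete transcript models, because nonsense-mediated decay transcripts, with a median length of 1299 nt, differed from other transcripts of their genes by -0.014 (-0.062 to 0.026) in 962 genes. Less unspliced or nuclear RNA in replicate 2 may underlie the pattern, as retained-intron transcripts, with a median length of 829 nt, differed by -0.37 (-0.39 to -0.35), lower in 2116 of 2610 genes. The decay transcripts are longer than the retained-intron ones, so a bias confined to the shortest models stays open. The intervals around the medians in this paragraph are not counting intervals. They describe spread over genes within this single pair of libraries, so they do not measure how far the differences would recur in other pools.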

How the results depend on the processing

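Spike-in scaling and the protein-coding restriction were chosen after seeing the data. Without one library no difference between libraries can be computed, and no paired analysis was possible because there is 1 group. Detected genes ranged from 11140 at 5 TPM to 18574 with posterior mean TPM. The number of lists apart was between 18 and 20 and held all 18 main ones, except at a minimum of 200 counts, where 19 of 35 were apart, 16 of them shared, and the hypothalamic list had too few members. Called pairs numbered 16 to 18. Total count scaling, size factors and posterior means gave 201, 194 and 190 genes at least 2-fold apart. The number depended on the count minimum: 474 (132 higher in replicate 2, 342 in replicate 1) at 20, 40 (10 and 30) at 200 and 1099 (386 and 713) with none, over 15680, 11353 and 24665 genes compared; the cause was not tested further. Protein-coding genes alone gave 119, of which 83 were higher in replicate 1. Spike-in scaling gave 535 (514 and 21), by its shift of all genes, which also put medians above 0 for pan-neuronal (0.39), myelin (0.18), thalamic (0.030), synaptic (0.27), imprinted (0.24) and brain disorder genes (0.42). Pearson's r was 0.984 with a pseudocount of 0.1, 0.990 for genes at 1 TPM and 0.994 with FPKM. The same top transcript was found in 92.1% of genes at 5 TPM and 95.2% at 50 TPM. A transcript with at least 80% was found in 36.3% at 50 TPM, in 29.8% with posterior means and in 34.6% to 37.3% with 1 replicate left out, where 1 library alone must pass. The protein-coding share was 81.8% by TPM, which divides by length. Other causes were not tested. Depth limits the hypothalamic and bone genes, several of which had under 50 counts.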

Other observations

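Several other gene groups differed little between the pools. Tubulins had a median log2 ratio of -0.02 over 12 genes, with Tuba1b at 953 and 976 TPM, although Tubb2a was at 1752 and 1422 TPM. Splicing regulators had a median of 0.05 over 18 genes, with Rbfox2 at 115 and 120 TPM, while Nova1 had a log2 ratio of -0.73 and Celf4 of -0.41. Both lists lay within the range of random lists. Heat shock, hypoxia and glycolysis, and reference genes had medians of 0.04, 0.07 and 0.05, also within that range. These lists of tubulins and splicing regulators, and the epithelial list below, were written after the main values had been seen, and the tubulins Tuba1a, Tubb3 and Tubb5 and the regulator Ptbp2 had already been inspected.

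Epithelial genes of nose, airway and skin were few and uneven. At a minimum of 5 counts their median log2 ratio was 0.46 over 13 genes, above the central 95% of random lists (-0.66 to 0.26), with 9 higher in replicate 2. Krt15 had 2 and 40 counts and Krtdap 0 and 14. The summed counts of the list had the opposite sign, -0.31, because Gnal, also expressed in striatum, holds most of them.

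Genomic DNA in replicate 1 was considered as a further candidate source of the noncoding signal. Summed counts over 1343 olfactory and vomeronasal receptor genes, which are largely silent in brain, were 170 in replicate 1 and 142 in replicate 2, a log2 ratio of -0.032 (-0.37 to 0.30). The interval met neither bound set in advance, and nasal tissue in replicate 2 could raise the same genes, so this possibility stays open.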
